A study of Homo sapiens with 6 samples.

How the data were processed

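Gene expression was measured in HCT116, an established human colorectal carcinoma cell line, on Affymetrix whole-transcript Gene ST arrays. Total RNA was extracted from cells in standard culture medium, and 100 ng was labelled with biotin, per the labels' protocols. The 6 arrays fall into 2 groups by their genotype label, with 3 arrays of the parental line and 3 of a derived mutant line described as having altered DNA methylation. The labels do not name the mutated gene, and it was not inferred from the data.

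The deposited values are on the log2 scale, 1 per probe set and array, made with robust multi-array average (RMA) and Partek, per the submitters' processing notes. The versions of these tools are not given in the sources used here. RMA corrects the background, makes the distributions of all arrays alike by quantile normalization and summarises the probes of each probe set. It therefore removes any difference in the total amount of RNA per cell between the lines and compresses changes of dim probe sets. Array medians lay between 6.88 and 6.93, with no missing values, and the values were used as deposited without further normalization. Sequencing depth does not apply to arrays, and the number of arrays limits the precision.

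The table holds 33297 probe sets. In the platform annotation used here, 19460 probe sets have 1 gene symbol, 1754 have several and 12083 are not named. Genes were named only from probe sets with 1 symbol, which gave 18417 genes. Of these, 769 had more than 1 such probe set, and each was represented by the probe set with the highest mean over all 6 arrays. Among those 769 genes, 0 had probe sets called in opposite directions and 120 had some called and others not. No table held here marks control probe sets, so all rows were tested, 558 of them identical to an earlier row. The gene IDs of 19429 single-symbol probe sets were found in the RefSeq gene table of assembly GRCh38.p14. That table was used only for chromosome and gene order, since the genome build behind the probe annotation is not given in the sources used here. XIST and Y-linked genes are not reported.

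Mutant minus parental differences were tested per probe set with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without covariates. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, and an adjusted p under 0.05 was called. The moderated variance had 4 residual and 2.16 prior degrees of freedom. Gene lists and chromosomes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists and over the 23 chromosomes. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.

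The groups, tests, gene lists, alternatives and rule for naming genes were fixed before the data were examined. The 33 lists hold 1053 distinct genes, of which 938 were measured, 36 of them matched by an older symbol. The rule names 7 writers and erasers of DNA methylation always. It also names the 12 genes with the largest called increase and the 12 with the largest called decrease of at least 1.5-fold whose arrays do not overlap between groups, and up to 2 called members per list and direction. Genes with certain forms of symbol, such as FAM or OR genes, were left out of the top 12, whether or not their function is known. This removed 4 genes from the lower side. Any gene named outside the rule is said to be chosen after its values were seen.

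The fit was tested on simulated data with the spread of the 33297 probe sets, 200 of them changed. Of the simulated changes, 61.2% were recovered at 1.5-fold, 79.1% at 2-fold and 98.5% at 4-fold, and 8 unchanged probe sets were called. With no change simulated, 1 probe set was called, and 0 of 200 simulated unchanged lists had an unadjusted camera p under 0.05. Those simulated genes varied independently, so this does not test camera under correlated genes.

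Alternatives covered quantile normalization again, array medians, 2 filters on dim probe sets, an intensity trend, an ordinary linear model, array weights, the replicate number as a block, each array left out, a minimum fold of 1.2 in the test, single-symbol probe sets only, the mean of a gene's probe sets and other set tests. Chosen after seeing the data were the exclusion of chromosomes 9, 13, 17 and 18 and the testing of identical probe sets once. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The DNA methylation of these lines was not analysed here.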

Results

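Expression profiles were obtained from 3 arrays of parental HCT116 cells and 3 arrays of a mutant HCT116 line with altered DNA methylation. The comparison asks how a gene mutation affects expression across the genome. The labels do not say that the mutant arrays come from independently derived clones. Effects of the mutation therefore cannot be told apart from other differences between the lines. Arrays of one group correlated across probe sets at 0.995 to 0.996, and arrays of different groups at 0.988 to 0.989; probe sets are not independent replicates. The first principal component held 59.6% of the variance and separated the lines.

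The 12 largest decreases named by the rule were of genes bright in parental cells, with fitted decreases of 21.9-fold to 151-fold. The mutant means of NETO2 (4.63), NRIP1 (4.26) and PROM1 (4.41) lay below 5, where RMA compresses differences, so fitted sizes near the background understate changes and their order is not fixed. MAL2, a membrane protein of apical transport (probe set 8148040), fell from 13.79 ± 0.03 to 6.55 ± 0.32 (mean log2 ± SD, n = 3 each; adjusted p = 7.87e-06). EREG, which encodes the EGF receptor ligand epiregulin (probe set 8095728), fell by 6.47 on the log2 scale, from 13.25 ± 0.04 to 6.78 ± 0.06 (adjusted p = 2.56e-07). The other decreases, as log2 changes, were VSNL1 -6.36, NETO2 -6.07, EHF -5.62, HBE1 -5.51, SQLE -5.20, NRIP1 -5.19, SYT1 -5.01, ACSL5 -4.85, PROM1 -4.73 and LMAN1 -4.46. EHF is an epithelial transcription factor, SQLE an enzyme of cholesterol synthesis, ACSL5 an acyl-CoA synthetase, and LMAN1 a cargo receptor of the early secretory pathway. FAM111B and OR51B4, named after their values were seen because the rule omits such symbols, changed by -5.26 and -6.24.

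Increases were smaller. EDA2R, a receptor of the TNF receptor family (probe set 8173299), rose from 5.69 ± 0.15 to 9.59 ± 0.08 (log2 ± SD, n = 3 each), a difference of 3.90 (adjusted p = 1.10e-05). MLLT11 rose by 3.60, GLIPR1 by 3.52, and TNFSF4 and TNFSF18, both TNF family ligands of chromosome 1, by 3.48 and 2.88. The cancer-testis gene CSAG1, one of a family of close copies that can share probes, rose by 3.30, the restriction factor BST2 by 3.14, NRG1, a ligand of ERBB receptors, by 2.93, and IFITM1, an interferon-induced membrane protein, by 2.43. PHYHD1 (2.92), in the shifted part of chromosome 9, KRTAP3-1 (2.63) and ANXA10 (2.60) also rose. The rule admits to these 24 genes only those whose groups do not overlap. Over all probe sets the groups did not overlap in 35.6%, where chance gives 10%.

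**Figure D1:**
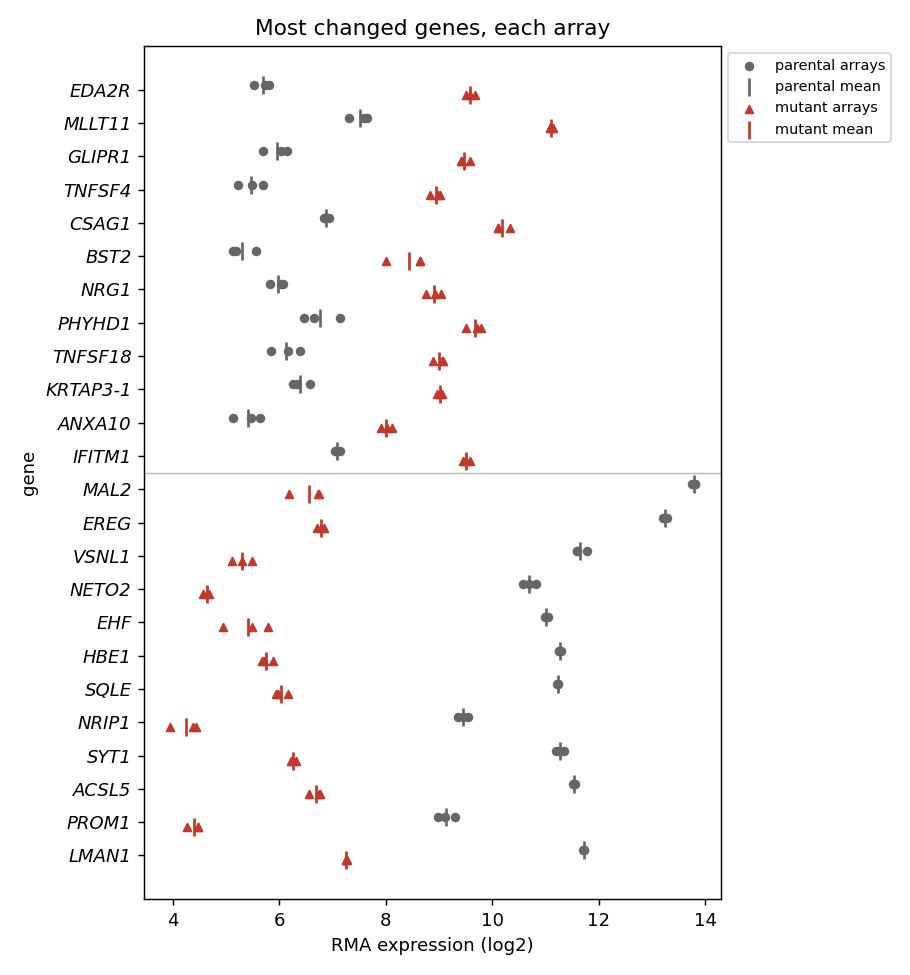
Log2 RMA expression (x axis) of the 12 genes with the largest increase and the 12 with the largest decrease named by the rule (y axis), with each of the 3 parental arrays (circles) and 3 mutant arrays (triangles) and the group means (vertical ticks). Genes whose groups overlap were not eligible; the parental and mutant means of MAL2 are 13.79 and 6.55, and those of EDA2R 5.69 and 9.59.

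In total 6166 of 33297 probe sets changed, 3447 higher and 2719 lower in the mutant. With at least a 1.5-fold change, 1736 probe sets remained, 846 higher and 890 lower. Counted by gene, 4773 of 18417 changed (2685 higher, 2088 lower). The balance turned with size: at 2-fold or more 147 genes were higher and 304 lower, at 4-fold or more 19 and 85, and at 16-fold or more 0 and 18. An unadjusted limma p under 0.05 was found for 9905 probe sets. The median change of all probe sets was -0.0055 on the log2 scale. The number of changed probe sets dropped to 1743 when the test required a fold of 1.2, to 4109 without parental replicate 2 and to 4037 without mutant replicate 2.

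Among the enzymes that write or remove DNA methylation, DNMT3B fell from 8.78 ± 0.07 to 8.39 ± 0.01 (log2 ± SD, n = 3 each), a change of -0.39 (adjusted p = 0.00493). The maintenance factor UHRF1 changed by -0.31 (adjusted p = 0.0274), and this call was lost in 7 of its alternatives. Its second probe set gave -0.01 (adjusted p = 0.959), but it is far dimmer, with a parental mean of 6.20 against 11.33. DNMT1 (0.10), DNMT3A (0.11), TET1 (0.25) and TET3 (0.04) had adjusted p-values of 0.181, 0.316, 0.197 and 0.774. TET2 gave -0.27 (adjusted p = 0.105) on its brightest probe set and -0.23 (adjusted p = 0.0276) on its other. Of 27 measured genes of the DNA methylation machinery, 4 rose and 4 fell, the same numbers when adjusted over the list alone. ZBTB33, a reader of methylated DNA, rose by 0.54 and AHCY, which clears the product of methyl transfer, changed by -0.32. As a list the machinery did not pass camera (adjusted p = 0.919). The labels do not name the mutated gene, so these levels do not check the line's identity.

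Gene classes often silenced by methylation did not pass camera as groups. Of 55 genes often methylated in colorectal cancer, 6 rose and 5 fell (6 and 6 when adjusted over the list alone; camera adjusted p = 0.488). The WNT antagonist DKK1 rose by 1.29 and the intermediate filament gene VIM by 0.93. CDH1, which encodes E-cadherin, fell by 1.36, and the kinase gene DAPK1 fell by 1.22. Of 50 cancer-testis and germline genes 1 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.774). The 2 were MAGEA4, which changed by 0.32 with its call lost in 10 of its alternatives, and TDRKH, a germline piRNA pathway gene, with -0.60. CSAG1, which rose by 3.30, is a cancer-testis gene that the list did not hold. Among 28 imprinted genes 5 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.434), though fry called the list lower (adjusted p = 0.00675), with GRB10 at 0.65 and PEG10 at -2.06. Of 16 protocadherin beta genes 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.555).

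Interferon-stimulated genes were higher in the mutant. Of 45 measured, 33 rose and 1 fell (38 and 1 adjusted over the list alone), with a median change of 0.71. Besides BST2 and IFITM1, the list's one decrease was SAMD9 (-0.54, adjusted p = 0.0212), whose call was lost in 5 of its alternatives. Camera gave an adjusted p of 2.78e-14 with the preset correlation, and adjusted p = 0.224 with an estimated correlation. Averaged over the list, the 3 mutant arrays stood 0.82, 0.80 and 0.80 above the parental mean, while the parental arrays lay between -0.08 and 0.07. Of 15 genes of antigen presentation by MHC class I, 11 rose and 0 fell, also when adjusted over the list alone. The median change was 0.46, with the trimming peptidase ERAP1 at 1.01 and the peptide transporter TAP1 at 0.70. Camera's adjusted p was 0.000179, and adjusted p = 0.243 with an estimated correlation. Among leukocyte markers 0 of 12 were higher and 1 was lower, also when adjusted over the list alone (camera adjusted p = 0.874).

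Epithelial junction and keratin genes were lower. Of 40 measured, 24 fell and 4 rose (29 and 5 adjusted over the list alone), with a median of -0.29. GRHL2, a transcription factor of epithelial junctions (probe set 8147697), fell from 8.70 ± 0.04 to 6.04 ± 0.10 (log2 ± SD, n = 3 each; adjusted p = 1.31e-05), and the keratin KRT23 fell by 2.65 as well. KRT80 (0.76) and OVOL2 (0.55), a repressor of mesenchymal genes, rose. Camera gave 2.84e-08 after adjustment, and adjusted p = 0.224 with an estimated correlation. Of 40 mesenchymal genes 8 rose and 4 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.849), with SNAI2, a repressor of epithelial genes, at 2.15 and ITGA5 at -0.61.

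Of 32 measured targets of p53, 16 rose, 2 fell and 14 did not pass (rose and fell: 18 and 3 adjusted over the list alone), with a median of 0.21. The kinase gene PLK2 rose by 1.98 and TP53I3 by 1.00, whereas the growth factor genes KITLG and GDF15 changed by -1.15 and -0.78. Camera gave an adjusted p of 0.00122, and adjusted p = 0.734 with an estimated correlation.

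Several metabolic and growth lists passed camera as lower. Of 25 cholesterol biosynthesis genes 13 fell and 2 rose (15 and 4 adjusted over the list alone; median -0.22), led by SQLE and by INSIG1 at -0.87, a regulator of sterol sensing; FADS2 rose by 0.54. Camera gave an adjusted p of 0.00311, and adjusted p = 0.734 with an estimated correlation. Of 38 genes of the unfolded protein and amino acid responses 15 fell and 3 rose (16 and 3 adjusted over the list alone; median -0.13). The cystine transporter SLC7A11 fell by 1.51 and PHGDH, an enzyme of serine synthesis, by 1.12, while the transcription factor gene ATF5 rose by 0.98. Its camera adjusted p was 0.000673, and adjusted p = 0.734 with an estimated correlation. Of 34 hypoxia and glycolysis genes 12 fell and 2 rose (12 and 4 adjusted over the list alone; median -0.09). The glucose transporter SLC2A3 fell by 1.74 and the peptide hormone gene ADM fell by 1.71. Camera gave 0.0113 after adjustment, 0.055 with array weights, 0.00101 to 0.852 over all its alternatives, and adjusted p = 0.851 with an estimated correlation. Of 43 S phase and DNA replication genes 16 fell and 4 rose (21 and 6 adjusted over the list alone; median -0.14). MCM4, a subunit of the replicative helicase, and TK1, in the shifted part of chromosome 17, both changed by -0.88. The list's adjusted p was 0.00149, and adjusted p = 0.851 with an estimated correlation.

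Most decreases among HOX genes, which set positional identity, lay in one cluster. Of 27 measured, 9 fell and 2 rose, also when adjusted over the list alone, and the median was -0.09. Of the 9, 8 belong to the HOXB cluster on chromosome 17, which had 10 measured members, with HOXB8 at -2.98 and HOXB6 at -1.54. The 8 HOXB genes with a mean log2 of at least 7 all lie in the shifted part of that chromosome. Their changes ran from -0.22 (HOXB13) to -2.98 (HOXB8), against a held-out median of -0.33 in that part. HOXA2 rose by 1.02. Camera gave an adjusted p of 0.00557, and adjusted p = 0.612 with an estimated correlation. Without genes of chromosomes 9, 13, 17 and 18, an exclusion chosen after the data were seen, the adjusted camera p was 0.991 (0.00108 to 0.991 over all its alternatives). Among the 17 genes left, 1 was lower and 2 were higher. The exclusion drops all 10 measured HOXB genes, so the lost call does not show that the shift of chromosome 17 explains their decrease.

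With the preset correlation 9 of 33 lists passed, 3 higher and 6 lower. With an estimated correlation camera called 0 lists, 3 having an unadjusted p under 0.05, and fry called 19. In the other splits of the 6 arrays up to 8 lists passed, and the S phase and hypoxia lists had as small a p in 3 and 4 of the 10 splits, the real one included.

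**Figure D2:**
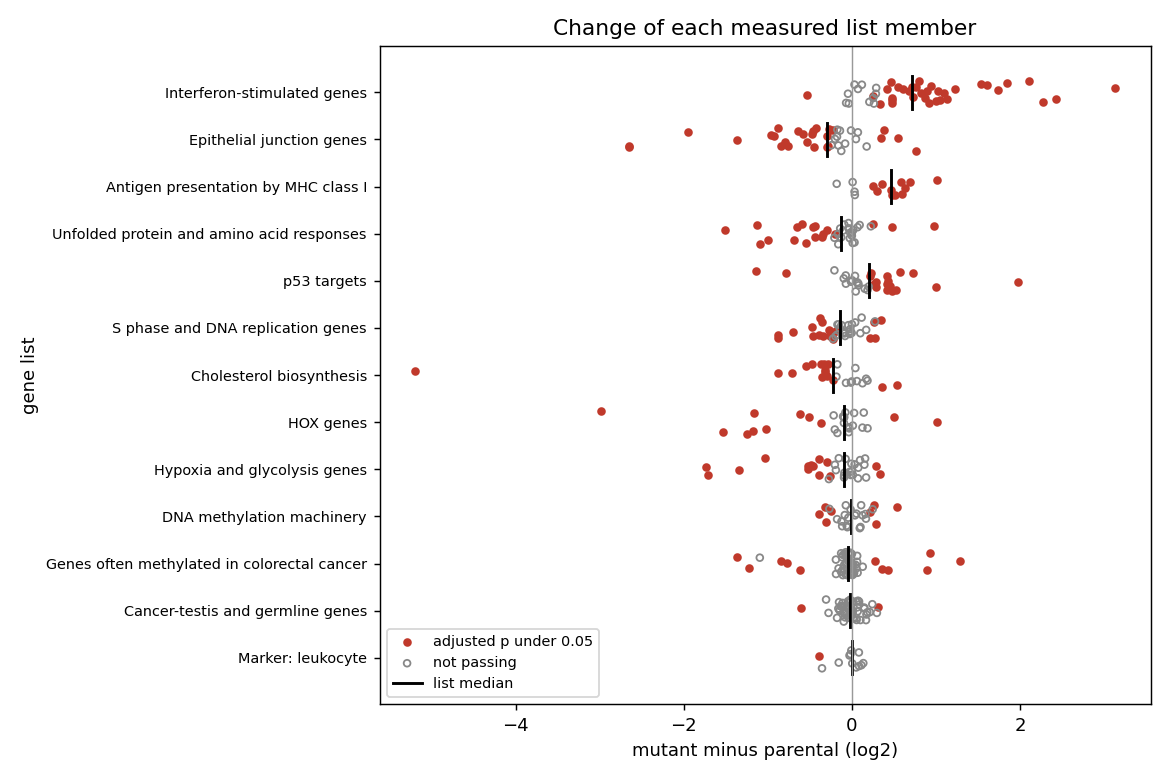
Mutant minus parental log2 change (x axis) of each measured member of the 9 lists that passed camera with the preset correlation and of 4 lists that did not (y axis); filled points passed the gene test, open points did not, and black bars are list medians. The interferon-stimulated list has its median at 0.71 and the epithelial junction list at -0.29.

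The other lists did not pass camera. Fry, which asks only whether a list's own genes move one way, called 10 of the lists that camera did not. Besides imprinted genes, it called lower the TGF-beta (adjusted p = 0.000586), WNT (0.00232), histone (0.00531), heat shock (0.00999) and ribosomal protein (0.0421) lists. It called higher the metallothionein (0.000906), NRF2 (0.0188), mesenchymal (0.0241) and intestinal differentiation (0.0321) lists. Genes of WNT signalling and intestinal stem cells went both ways, with 6 of 31 higher and 5 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.555). BMP4 rose by 1.32, PROM1 fell, and the WNT receptor ligase gene RNF43, in the shifted part of chromosome 17, fell by 3.88. Among 32 NF-kB targets and inflammatory cytokines, 11 rose and 3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.515), with the chemokine CCL5 up by 1.94 and IL18 at -4.03. Of 27 TGF-beta targets 4 rose and 8 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.325), including ID2 at -1.71. Of 44 intestinal differentiation genes 7 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.555), with the brush border peptidase DPP4 up by 1.41. Of 36 NRF2 and xenobiotic genes 10 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.509). ABCC3, a drug transporter, rose by 1.01.

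Among cell growth lists, 8 of 40 mitosis genes rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.670). Of 36 MYC targets and ribosome biogenesis genes 1 rose and 2 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.515). Cytosolic ribosomal protein genes had 3 of 38 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.176); RPL35 and RPL7A, both higher at 0.32 and 0.31, lie in the shifted part of chromosome 9. Of 27 replication-dependent histone genes, whose near-identical copies can share probes, 3 rose and 7 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0966). Of 18 heat shock genes 2 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.0827), HSPH1 falling by 1.74. Metallothionein and zinc genes had 3 of 10 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0966). Of 43 genes of chromatin repressor complexes 9 rose and 10 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.849), with CBX5, a heterochromatin protein, at 0.95 and JARID2, a partner of the Polycomb complex, at -0.74.

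Marker lists of other cell types did not pass camera. Fibroblast markers had 1 of 12 higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.555), and hepatocyte markers 0 of 12 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.515). Endothelial markers (9 measured), neural markers (9) and squamous epithelium markers (8) had 0 higher and 0 lower, also when adjusted over the list alone, with camera adjusted p-values of 0.690, 0.919 and 0.919. Median, mean and test direction differed in sign for 7 lists, which were the NF-kB, mitosis, intestinal differentiation, mesenchymal, chromatin repressor, DNA methylation machinery and neural marker lists.

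By chromosome, camera called chromosome 9 higher and chromosome 17 lower. On chromosome 9, 226 of 732 genes rose and 43 fell (254 and 49 adjusted over the list alone), with an adjusted camera p of 0.000351. On chromosome 17, 244 of 1067 genes fell and 103 rose (274 and 128 adjusted over the list alone), with an adjusted camera p of 0.0171. Both calls were lost at adjusted p = 0.999 with an estimated correlation, where camera called 0 chromosomes and 0 had an unadjusted p under 0.05; fry called 5. Chromosome 18, with 66 of 264 genes lower and 35 higher (67 and 38 adjusted over the list alone), had an adjusted p of 0.0615. The plot of genes in chromosome order, drawn after these values were seen, shows shifts over parts of chromosomes 9, 13, 17 and 18.

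**Figure D3:**
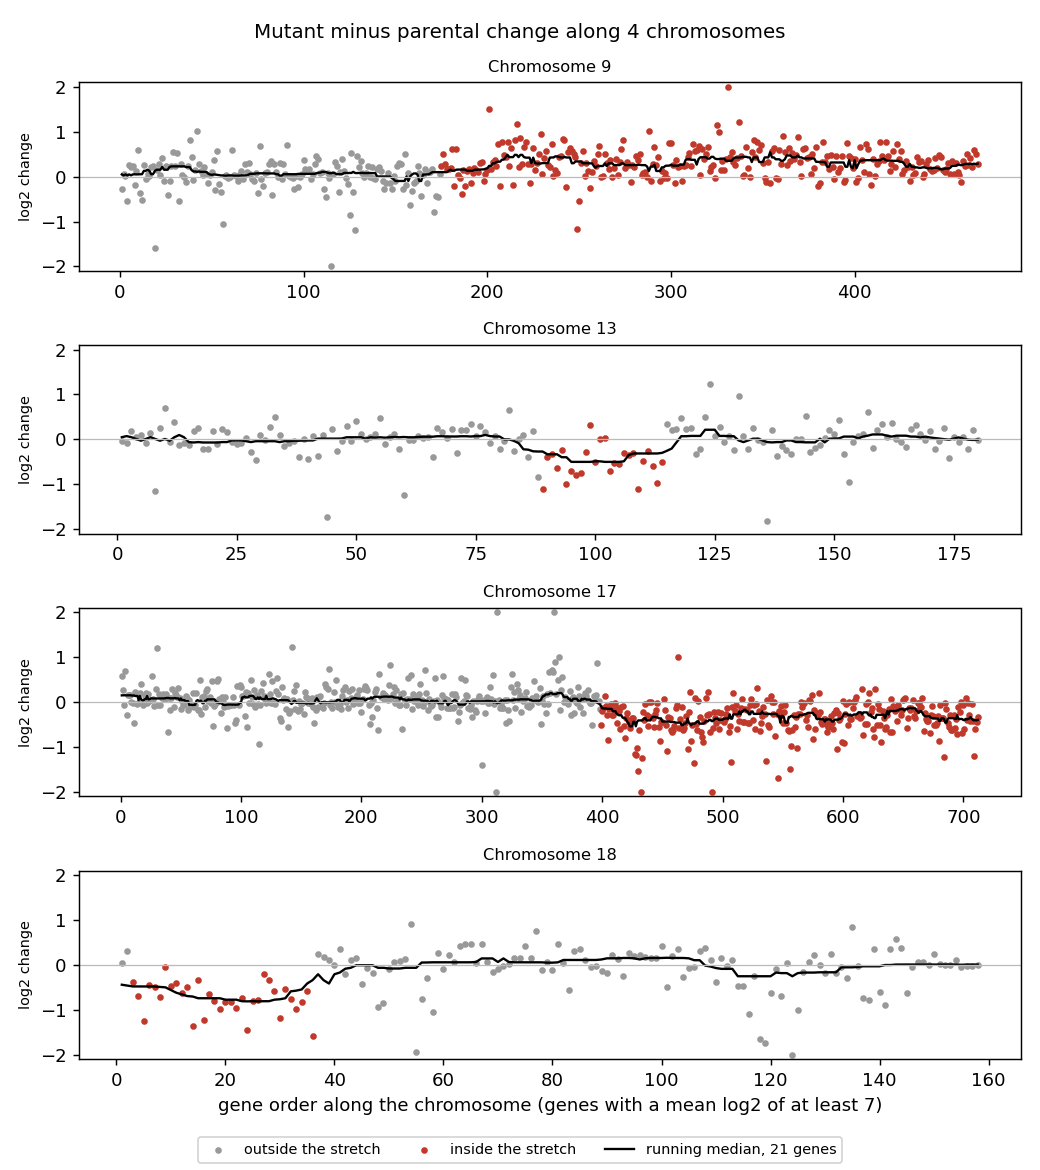
Mutant minus parental log2 change (y axis, points beyond 2 drawn at 2) of genes with a mean log2 of at least 7, in their order along chromosomes 9, 13, 17 and 18 (x axis, GRCh38.p14); lines are running medians over 21 genes. Red points lie in the stretch placed on each chromosome, where the medians of genes not used for placing were 0.29, -0.50, -0.33 and -0.81.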

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

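The counts of probe sets, genes, lists and chromosomes were recomputed under each alternative, and of 144 named genes 0 had a call that reversed direction. The methylation machinery list and chromosome 22, called by neither camera nor fry, were lower by camera and higher by fry. Requiring a fold of 1.2 in the test lowered the probe sets changed from 6166 to 1743 and the genes changed from 4773 to 1442, since that test is stricter by construction, and the share of higher genes from 56.2% to 48.2%. With an estimated correlation camera called 0 lists and 0 chromosomes, while fry, which does not compare a list with other genes, called 19 lists and 5 chromosomes. Leaving out each array in turn gave 4037 to 4644 probe sets, 1656 to 1720 at 1.5-fold, 3198 to 3627 genes, 9 to 10 lists and 2 to 3 chromosomes. The lowest probe set counts came without mutant replicate 2 (4037) and without parental replicate 2 (4109). Fewer arrays lower the power, and whether those arrays differ otherwise was not tested.

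The replicate numbers gave no sign of pairing. Deviations from the group means correlated at 0.043, -0.013 and 0.003 for equal numbers and between -0.064 and 0.06 for others. How the arrays were handled is not shown by these values. With the replicate number as a block 3395 genes were called, 3336 of them shared with the 4773, all in the same direction. Without chromosomes 9, 13, 17 and 18, an exclusion chosen after seeing the data, 3804 genes changed and 8 lists passed. For these 144 genes, 2417 gene values under alternatives gave 2265 with the same call, 139 that lost it and 13 that gained it. Arrays have no depth, and genes near the background, where RMA compresses differences, are measured less precisely.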

Other observations

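The stretch tests, the test of shared probes and the leukocyte test were chosen only after the result was seen, and so were the gene groups of the next paragraph. The stretches were searched under 2 definitions, the second written after the output of the first had been read, and how the chromosome 19 result is read was also revised after its value was seen.

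Of 10 measured ligands of the EGF receptor family, 6 did not pass. EGF (0.76, adjusted p = 0.00165) and NRG1 rose, and EREG and NRG4 (-1.16, adjusted p = 0.0192, its call lost in 4 of its alternatives) fell. EGF (5.11 in parental and 5.86 in mutant cells) and NRG4 (5.12 and 3.96) are dim, and the group was not tested for enrichment. Among 9 measured MHC class II genes, HLA-DPA1 rose by 1.42 (adjusted p = 0.00258) and HLA-DPB1 by 1.59 (adjusted p = 0.000906). The other 7 did not pass, including their regulator CIITA (-0.12, adjusted p = 0.279). HLA genes are close copies that can share probes. Of 494 zinc finger genes named ZNF, 100 rose and 63 fell, but at 2-fold or more 3 were higher and 31 lower, 23 of the 31 on chromosome 19, which holds 237 of the 494; the difference in share was not tested. ZNF83 changed by -3.64, ZNF28 by -3.20 and ZNF468 by -3.68, all named after their values were seen.

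The first pattern is a shift of whole chromosome parts. Stretches were placed with every other gene and read on the rest, and the gene order is that of GRCh38.p14. On chromosomes 9, 13, 17 and 18 the held-out medians inside were 0.29, -0.50, -0.33 and -0.81, each with an adjusted permutation p of 0.00575 (unadjusted 0.001, the smallest 1000 permutations can give). At least 83.6% of held-out genes inside moved in the stretch's direction, which argues against a few strongly changed genes. On chromosome 9 the share was 79.2% under the first definition, with a median of 0.23. A change in copy number of chromosome segments may account for the shifts. Outside, the largest absolute median was 0.0466, but a small median does not show that every part outside was unshifted. On chromosome 18, ATP8B1 (-1.645), NEDD4L (-1.743), MALT1 (-0.6161), SEC11C (-0.6947) and LMAN1 (-4.455) lie close together outside the stretch. ZNF532 (-0.08923) and RAX (0.04618) lie among them. ONECUT2 (-0.4666), FECH (-0.4724), NARS1 (-1.105) and ATP8B1-AS1 (-0.2537) come just before this run, and PMAIP1 (-0.9972) just after it. Whether the run is a further shifted part was not tested. Chromosomes 9, 13, 17 and 18 passed under both definitions, and chromosomes 2 and 19 under the first alone. X passed under the second alone (adjusted permutation p = 0.00919, against 0.0657 under the first). Its held-out median was 0.21, with 84.4% of held-out genes inside higher. X was kept where chromosomes 9, 13, 17 and 18 were left out. DNA copy number was not analysed here, and the mutation's own effect stays open as untested.

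The second pattern is that neighbouring genes changed together, with 9 adjacent pairs of genes higher at least 2-fold against a mean of 1.16 in 10000 shuffles, and 7 against 0.953 for different name roots without chromosomes 9, 13, 17 and 18 (both permutation p = 0.0001). Among genes lower at least 2-fold there were 37 adjacent pairs, against a mean of 5.01 in 10000 shuffles, and without chromosomes 9, 13, 17 and 18 there were 13 pairs with different name roots, against a mean of 3.43 and a highest of 12 (permutation p = 0.0001, the smallest the shuffles can give). The shuffles moved the calls over all genes, dim ones included. Any clustering of bright genes along chromosomes was therefore not allowed for, and these permutation p-values may be too small. The 13 pairs carry different name roots, which argues against probes shared by copies of a gene family, but probe sequences were not compared. Shared probes could account for other pairs, such as those of the OR51B genes of chromosome 11, which was not tested. HBE1, on the same chromosome but with another name root, changed by -5.51. The chromosome 19 stretch from ZNF808 to ZNF468 was picked as the longest chain of lower zinc finger genes, so its share of lower genes is no support. In it 7 of 8 genes fell at least 2-fold, and ZNF611 inside it did not (0.17, 95% interval -0.016 to 0.366). Loss of that stretch cannot be told apart from silencing of its genes. Of the genes bright in parental cells (mean log2 at least 7), 0 had an interval wholly above -0.3, but all 5 such genes were picked as lower. ZNF611 has an interval above -0.3, but its parental mean of 6.81 is below that cut, and 1 gene does not decide the question.

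The third pattern is the rise of interferon-stimulated genes. Without chromosomes 9, 13, 17 and 18 the list's median was 0.76, against 0.71 with them, so the shifted stretches do not account for it. Leukocytes in the cultures would raise their markers, and the upper 95% bound of the mean change of 12 markers was 0.0711. That bound comes from the spread across the 12 genes and holds no spread between arrays. Raised transcripts of interferon genes remain a possible explanation resting on 1 of 16 measured, IFNL3 (0.24, adjusted p = 0.0465). Over all genes, 2685 of 18417 were called higher, so 1 of 16 is no excess. The call of IFNL3 was lost in 11 of its alternatives, and its near-identical copy IFNL2 can share probes. No culture treatment or virus was tested, and a biological origin in altered methylation stays untested.

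Of the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05, 1 split, the real one, gave as many changed probe sets, probe sets at 1.5-fold, genes, lists and chromosomes. The real counts were 6166, 1736, 4773, 9 and 2, and the highest of the other splits were 0, 0, 0, 8 and 0. Every other split sets 2 arrays of one line and 1 of the other against the reverse. Part of the difference between the lines therefore remains in each, and the 8 lists do not measure chance alone. That difference also widens the spread within the mixed groups and so lowers the number of calls. The counts of 0 therefore do not measure chance either. The S phase list had as small a p in 3 of the 10 splits and the hypoxia list in 4, the real one included, and the other 7 lists only in the real split.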
